A study of Mus musculus with 4 samples.

How the data were processed

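The series holds 4 samples of whole MC38 tumours from C57BL/6J mice treated with anti-PD-1, of which 2 are gene expression libraries and 2 are TCR libraries, each kind made from 1 WT and 1 p53 KO tumour sample. The samples were grouped by the tumour genotype and library type that their titles give. The TCR libraries were analysed, and the gene expression libraries were not analysed here. The number of mice behind each library is not given in the sources used here.

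The authors deposited, for each TCR library, a list of filtered contigs with the V and J gene, CDR3 sequence, clonotype and cell barcode of each assembled chain. Reads and UMIs per contig are deposited as whole-number counts, per the file headers, and were not normalized. Per the submitters' processing notes, Cell Ranger 6.1.1 and the mm10 build were used. The version of its TCR reference is not given in the sources used here. All 733 WT and 709 p53 KO contigs were marked as high-confidence, full-length and productive chains of called cells. The contigs rested on 14957044 reads in WT and 19853340 in p53 KO, and on 4280 and 4138 UMIs. The median was 4 UMIs per contig in WT and 5 in p53 KO. The number of cells limits the precision: with 277 and 259 paired cells, a count of 0 allows shares of up to 1.08% and 1.16% (3 counts of the total).

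A paired cell is a barcode with 1 or more TRA and 1 or more TRB contigs. A clonotype is the deposited clonotype identifier. Where a cell or clonotype had several contigs of a chain, the one with most UMIs was used. Gene usage, CDR3 length, hydropathy and J alpha position were counted over clonotypes, and clonal expansion and invariant chains over paired cells. Hydropathy is the mean Kyte-Doolittle value of the CDR3 beta without its first 4 and last 4 residues, positive if above 0. Invariant NKT chains were TRAV11 or TRAV11D with TRAJ18, and MAIT chains TRAV1 with TRAJ33. To compare numbers of clonotypes, the larger library was drawn down to 259 paired cells 1000 times. Usage difference between libraries is the total variation distance, which is 0% for identical and 100% for disjoint usage, and was set beside 1000 random deals of the pooled clonotypes to sets of the same sizes.

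Genes were named by a rule fixed before the data were examined. For each of TRBV, TRBJ, TRAV and TRAJ it takes the 3 genes with the highest share of clonotypes in each library. It adds, among genes in 20 or more clonotypes over both libraries, up to 3 with the highest and 3 with the lowest ratio of p53 KO to WT share, if the ratio is at least 1.5 or at most its inverse. It also takes the 5 largest clonotypes of each library, receptors found in both libraries if 5 or fewer, and the invariant chains. Ties were broken by gene name or clonotype identifier. Of 156 gene names, 155 matched the RefSeq annotation of GRCm38.p6, the assembly of mm10, which gave the coordinates. TRBV12-2+TRBV13-2 was not matched.

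With 1 library per genotype no test, p-value or standard error was computed. Shares are given with exact (Clopper-Pearson) 95% intervals, which cover counting error only. No doublet caller was run. Possible multiplets, with 2 or more TRB or 3 or more TRA contigs, stayed in and were left out as an alternative. They were 14 of 408 WT cells (3.43%) and 22 of 392 p53 KO cells (5.61%), all by their TRB contigs.

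The naming rule was tested on simulated TRBV usage in libraries of the same numbers of clonotypes. With no true change, 27.3% of 333 genes in 20 or more clonotypes passed the ratio of 1.5, and the interval held the true share in 95.8%. In another setting the p53 KO shares of chosen common genes were multiplied by 3, and all shares were then rescaled to sum to 100%. The true change of the chosen genes was thus under 3-fold, and it passed in 93% of 100 cases.

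Alternatives fixed beforehand were other definitions of a clonotype, all cells in place of paired cells, and a minimum of 3 UMIs per contig. Also fixed beforehand were leaving out possible multiplets, equal cell numbers and cells in place of clonotypes. Leaving out the 10 largest clonotypes was another, with the remaining cells counted in place of clonotypes. For invariant and common chains, a last one took all contigs in place of the top one. Pooled V gene names, counting each alpha chain nucleotide sequence once, leaving out 2 p53 KO alpha chains, and leaving out invariant chains in a clonotype of another alpha chain were added after seeing the data. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used.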

Results

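MC38 is a mouse colon carcinoma cell line that grows as a tumour in C57BL/6J mice. Tumours of wild-type (WT) MC38 cells and of MC38 cells with a p53 knockout (p53 KO) were compared in mice treated with anti-PD-1, an antibody that blocks an inhibitory receptor of T cells. Whole tumours were loaded on the 10x Chromium 5' platform, which tags the RNA of each cell with a barcode and each RNA molecule with a unique molecular identifier (UMI). T cell receptor (TCR) libraries were made from the same material. The deposited TCR contigs of 1 WT and 1 p53 KO library were analysed, and the 2 matching gene expression libraries were not analysed here. The question put to these files was how the repertoire of tumour T cells differed between the 2 tumour genotypes under anti-PD-1.

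The WT library held 733 assembled receptor chains in 408 cells and the p53 KO library held 709 chains in 392 cells. Both chains of the receptor were found in 277 WT cells (67.9%, exact 95% interval 63.1 to 72.4) and in 259 p53 KO cells (66.1%, 61.1 to 70.7). These are called paired cells. The libraries rested on 4280 and 4138 UMIs, with a median of 8 UMIs per cell in WT and 9 in p53 KO. Each genotype had 1 library, so no difference has a replicate check and no test was made. All intervals of shares are exact binomial (Clopper-Pearson) intervals that cover counting error only. The p53 knockout itself cannot be checked in receptor chains, and the genotypes are those of the labels.

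The p53 KO library was more dominated by a few T cell clones. The 10 largest clonotypes, which are groups of cells with the same receptor, held 83 of 259 paired cells in p53 KO (32.0%, 26.4 to 38.1) and 42 of 277 in WT (15.2%, 11.2 to 19.9). The largest clonotype held 28 cells in p53 KO (10.8%, 7.30 to 15.2) and 6 cells in WT (2.17%, 0.799 to 4.65). Clonotypes of 10 or more cells held 54 p53 KO cells in 3 clonotypes (20.8%, 16.1 to 26.3). In WT they held 0 of 277 cells, but a large WT clone sampled in fewer than 10 cells would not be counted here. The intervals treat cells as independent, although the 54 cells come from 3 clonotypes, so they do not measure how shares of clones vary. Clonotypes of 2 to 4 cells held a larger share in WT. They had 29.6% of paired cells (24.3 to 35.4) against 17.8% in p53 KO (13.3 to 23.0). The p53 KO total of 259 includes the 54 cells of the 3 large clonotypes, which lowers the share of every other class.

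**Figure D1:**
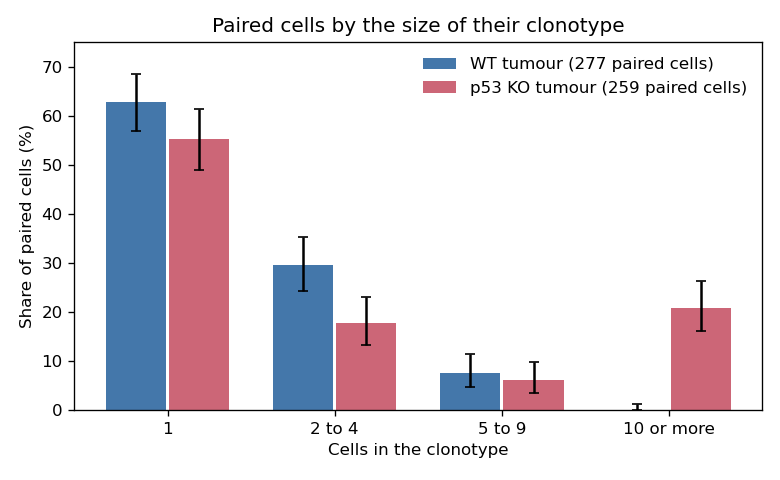
Share of paired cells (%) by the number of cells in their clonotype, for the WT and the p53 KO tumour library. Bars are shares and lines are exact 95% intervals for counting error. Clonotypes of 10 or more cells held 20.8% of the p53 KO cells and 0 of the 277 WT cells.

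The share of paired cells in any clonotype of 2 or more cells differed less. It was 37.2% in WT (103 of 277, 31.5 to 43.2) and 44.8% in p53 KO (116 of 259, 38.6 to 51.1), and the intervals overlap. The difference of 7.60 percentage points was 0.880 when all cells with any chain were counted and 16.4 when each chain needed 3 or more UMIs. At an equal number of 259 paired cells, WT held a median of 199 clonotypes (central 95% of 1000 draws, 196 to 204) and p53 KO held 168. The range of draws reflects only which of the 277 WT cells were left out, and is not a sampling interval. The labels do not give the number of mice behind each library, and T cell clones differ between mice, so the shares and numbers of clonotypes depend on that number.

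Of the 5 largest p53 KO clonotypes, 4 had an alpha chain of the TRAV7 family, each from a different gene, and all 5 had different TRBV genes. The largest, of 28 cells, joined TRAV7D-3 and TRAJ37 (CDR3 alpha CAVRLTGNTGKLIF) to TRBV1 and TRBJ2-2 (CDR3 beta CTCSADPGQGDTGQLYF). CDR3 is the part of each chain that is made at the junction of its V and J segments and lies closest to the bound peptide. The second, of 16 cells, paired TRAV7-6 and TRAJ43 (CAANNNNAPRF) with TRBV19 and TRBJ2-1 (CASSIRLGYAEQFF). Its beta chain was found in 31 cells in all, 14 of them with no alpha chain. The beta chain of the largest clonotype was found in 30 cells, 2 of them with no alpha chain. The order of these clonotypes thus depends on counting paired cells. The third, of 10 cells, paired TRAV7-4 and TRAJ33 (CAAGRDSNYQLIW) with TRBV5 and TRBJ2-1 (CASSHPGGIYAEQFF). The next were a clonotype of 6 cells with TRAV9D-3 and TRBV2 (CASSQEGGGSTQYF) and one of 5 cells with TRAV7-3 and TRBV26 (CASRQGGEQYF). The last was tied in size with 1 that carried TRAV3D-3 and TRBV5, so the TRAV7 and TRBV counts above depend on how the tie was broken. In WT the largest clonotype, of 6 cells, paired TRAV3D-3 and TRAJ23 (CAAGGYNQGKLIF) with TRBV12-2+TRBV13-2 and TRBJ2-2 (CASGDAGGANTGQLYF). WT clonotypes of 5 cells carried TRBV3 (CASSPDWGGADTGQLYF), TRBV17 (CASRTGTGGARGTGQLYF) and TRBV15 (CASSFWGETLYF), and the fifth, 1 of 3 tied at 4 cells, carried TRBV13-1 (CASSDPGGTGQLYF).

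Use of V and J genes was counted once per clonotype, so that a large clone did not weigh more than a single cell. For the beta chain, encoded on chromosome 6, the leading genes were largely shared. TRBV12-2+TRBV13-2, a combined name in the deposited contigs, was in 12.8% of WT clonotypes (8.60 to 18.1) and 11.3% of p53 KO clonotypes (6.95 to 17.1). All contigs of this name carried the CDR1 and CDR2 of TRBV13-2. TRBV13-1 was in 9.005% of WT (5.51 to 13.7) and 7.14% of p53 KO clonotypes (3.75 to 12.1), where it tied at 12 clonotypes with TRBV3 and TRBV5, the last seen in 13 WT clonotypes. TRBJ2-7 led the J genes in both, with 16.6% in WT (11.8 to 22.3) and 22.6% in p53 KO (16.5 to 29.7). TRBJ2-5 stood at 13.7% and 11.9%, and TRBJ2-1 at 10.4% and 13.7%. By cells, TRBJ2-1 was in 27 of 277 WT and 54 of 259 p53 KO cells, as 2 of the 3 largest p53 KO clonotypes carry it, and TRBV12-2+TRBV13-2 in 39 and 21.

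Of the 6 TRBV and 8 TRBJ genes found in 20 or more clonotypes, 4 had a p53 KO share lower than WT by the factor of 1.5 set for naming, and 0 had a higher one. TRBV3 (chromosome 6, 41048394 to 41048824 in mm10) was in 27 of 211 WT clonotypes (12.8%, 8.60 to 18.1) and 12 of 168 p53 KO clonotypes (7.14%, 3.75 to 12.1). Its ratio of shares, 0.558, was 0.313 by cells (41 of 277 and 12 of 259) and 0.333 with 3 or more UMIs per contig. TRBV1 (40891296 to 40891885) was in 10.9% of WT (7.04 to 15.9) and 6.55% of p53 KO clonotypes (3.31 to 11.4). Counted by cells its order turned, with 28 of 277 WT cells and 38 of 259 p53 KO cells, 28 of which came from the largest clonotype. TRBJ2-2 (41542957 to 41543007) was in 11.4% of WT (7.43 to 16.5) and 4.76% of p53 KO clonotypes (2.08 to 9.17), but by cells in 41 of 277 WT and 35 of 259 p53 KO cells, which moves the ratio of shares from 0.419 to 0.913. TRBJ2-3 (41543223 to 41543271) was in 9.48% (5.89 to 14.3) and 5.36% (2.48 to 9.93) of clonotypes. The intervals of all 4 overlap. In simulated libraries with no true change, 27.3% of TRBV genes in 20 or more clonotypes passed this factor, so passing it does not set TRBV3 or TRBV1 apart from counting error. TRBJ genes were not simulated.

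**Figure D2:**
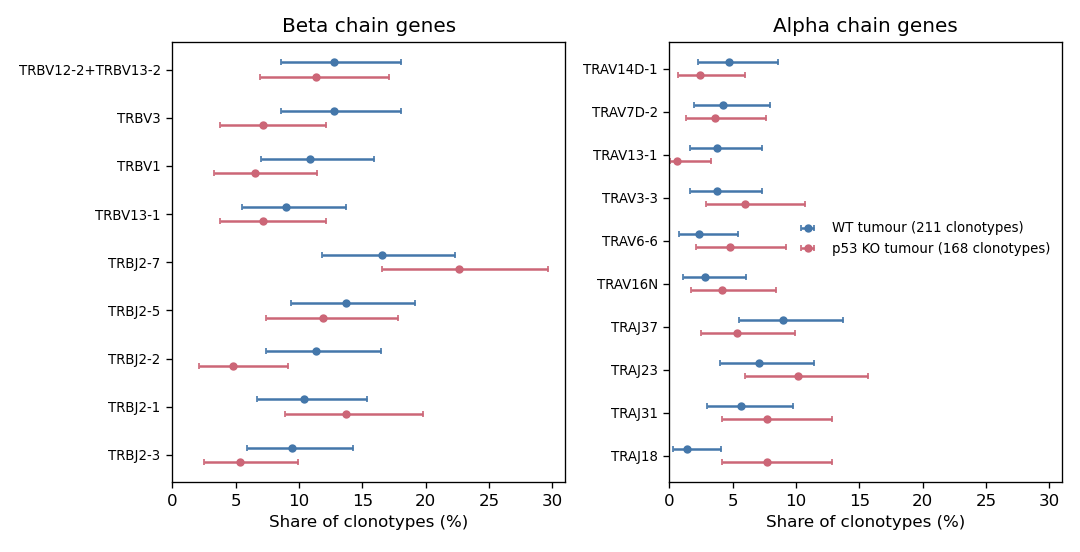
Share of clonotypes (%) that use each named V or J gene in the WT (211 clonotypes) and p53 KO (168 clonotypes) library. Points are shares and lines are exact 95% intervals for counting error. The intervals of TRAJ18 lie apart, at 1.42% in WT and 7.74% in p53 KO, and those of the other named genes overlap.

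For the alpha chain, encoded on chromosome 14, TRAJ18 was in a larger share of p53 KO clonotypes. TRAJ18 (54200777 to 54200842) was in 3 of 211 WT clonotypes (1.42%, 0.294 to 4.10) and 13 of 168 p53 KO clonotypes (7.74%, 4.18 to 12.9), and was the only one of 156 gene names whose intervals lay apart. Of the 13 p53 KO clonotypes, 5 had an invariant natural killer T cell chain and 4 had 1 shared TRAV6-6 chain (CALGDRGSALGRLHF), which was singled out after its values were seen. Without these, TRAJ18 was in 4 of 159 p53 KO clonotypes (2.52%, 0.690 to 6.32). With 3 or more UMIs per contig it was in 2 of 136 WT and 4 of 102 p53 KO clonotypes, and the ratio of shares fell from 5.44 to 2.67. Each alpha chain nucleotide sequence counted once, it was in 3 of 206 WT and 9 of 151 p53 KO chains. On this count, and on that with 3 or more UMIs, the exact intervals of the libraries overlap. Counted by cells, TRAJ18 was in 12 of 277 WT cells and 15 of 259 p53 KO cells, since 2 of the 5 largest WT clonotypes used it. TRAJ37 (54181518 to 54181577) was in 9.005% of WT (5.51 to 13.7) and 5.36% of p53 KO clonotypes (2.48 to 9.93), and its order also turned when cells were counted, because the largest p53 KO clonotype carries it. TRAJ23 was in 7.11% and 10.1%, and TRAJ31 in 5.69% and 7.74%.

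No TRAV gene reached 20 clonotypes over both libraries. The leading WT genes were TRAV14D-1 with 10 WT and 4 p53 KO clonotypes, TRAV7D-2 with 9 and 6, and, tied at 8 WT clonotypes, TRAV13-1 with 1, TRAV3-3 with 10 and TRAV9-4 with 2 p53 KO clonotypes. The leading p53 KO genes were TRAV3-3 with 8 WT and 10 p53 KO clonotypes, TRAV6-6 with 5 and 8, and, tied at 7 p53 KO clonotypes, TRAV16N with 6, TRAV3D-3 with 7 and TRAV6N-7 with 7 WT clonotypes. TRBV5, TRAV9-4, TRAV3D-3 and TRAV6N-7 fall outside the gene naming rule and were added after their values were seen. Counted once per alpha chain nucleotide sequence, TRAV3-3 had 8 WT and 6 p53 KO chains and TRAV6-6 had 5 and 5, since 4 of the 8 TRAV6-6 clonotypes in p53 KO shared the chain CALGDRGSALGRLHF. The summed difference in usage between the libraries was 17.5% for TRBV and 14.97% for TRBJ. Random dealing of the pooled clonotypes gave medians of 17.8% and 13.1%, and the central 95% of deals ended at 24.1% and 19.7%. For TRAV and TRAJ the observed differences were 41.2% and 32.2%, against dealt medians of 34.9% and 24.9% and upper ends of 40.6% and 31.5%. The TRAJ value lay above the dealt range under all 5 alternatives fixed beforehand. The TRAV value did so by cells and over all cells with the chain (40.3% against an upper end of 38.6%). It also did so without the 10 largest clonotypes, again by cells (40.7% against 38.7%). Alternatives counted by cells deal the cells of a clone as if independent, which narrows the dealt range. The TRAV value lay within the range without possible multiplets (41.2% against an upper end of 42.8%), with 3 or more UMIs per contig (48.3% against 51.5%) and with TRAV genes pooled by family (16.7% against 21.6%). Dealing treats clonotypes as independent, but some p53 KO clonotypes shared 1 alpha chain. With each alpha chain nucleotide sequence counted once (206 in WT and 151 in p53 KO), both values lay within the dealt range, at 39.4% against 43.0% for TRAV and 30.1% against 32.3% for TRAJ. Random dealing describes these 2 libraries and says nothing of other mice.

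Invariant natural killer T (NKT) cells, which recognise lipids through an alpha chain of TRAV11 joined to TRAJ18, were found in the p53 KO library. Their alpha chain was in 6 of 259 paired p53 KO cells (2.32%, 0.855 to 4.97) and in 0 of 277 WT cells, which allows a share of up to 1.08%. All 6 cells had the CDR3 alpha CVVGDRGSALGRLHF, written by 4 different nucleotide sequences, with 6 different beta chains. In 5 of the 6 the beta chain used TRBV13-1, TRBV29 or TRBV12-2+TRBV13-2, genes among those usual for this cell type. The sixth used TRBV17 and belonged to a clonotype of 2 cells with another alpha chain, which that cell also carried with 1 UMI. Without that cell the p53 KO share was 1.93%. The invariant chain itself had 1 to 3 UMIs in each cell. A minimum of 3 UMIs, which was not tried for these chains, would remove most of the 6 cells. The intervals of both libraries overlap, so the difference is at the limit of this depth.

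The alpha chain of mucosal-associated invariant T (MAIT) cells, TRAV1 joined to TRAJ33, was in 0 of 277 WT and 0 of 259 p53 KO paired cells, which allows shares of up to 1.08% and 1.16%. Neither library held a contig of gamma delta T cell receptors or of immunoglobulins, as all contigs were TRA or TRB. Whether these TCR libraries could hold other chains was not tested, so this says nothing of gamma delta T cells or B cells.

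The mean length of the CDR3 beta over clonotypes was 13.95 amino acids in WT (SD 1.53 over 211 clonotypes) and 14.08 in p53 KO (SD 1.42 over 168 clonotypes). A CDR3 beta of 14 or more amino acids was found in 64.0% of WT clonotypes (57.1 to 70.5) and 69.6% of p53 KO clonotypes (62.1 to 76.5), with overlapping intervals. The share was higher in p53 KO under all 5 alternatives. Counted by cells it was 62.5% in WT and 74.1% in p53 KO, which raised the difference from 5.66 to 11.7 percentage points. The 3 largest p53 KO clonotypes, of 54 cells, all have a CDR3 beta of 14 or more amino acids. Without the 10 largest clonotypes, also by cells, the difference was 8.47 points. The middle of the CDR3 beta had a positive mean hydropathy in 14.7% of WT (10.2 to 20.2) and 14.9% of p53 KO clonotypes (9.87 to 21.2). The order of these 2 shares turned under 4 of the 5 alternatives tried, so no direction is given.

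**Figure D3:**
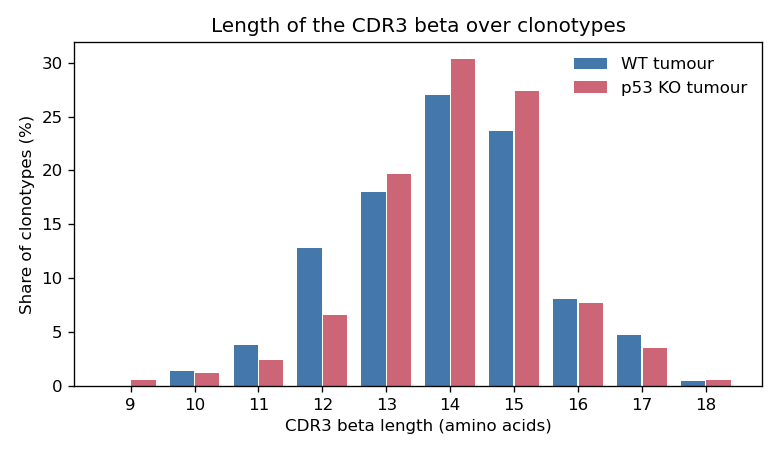
Length of the CDR3 beta in amino acids against the share of clonotypes (%) in the WT and p53 KO library, each clonotype counted once. Lengths centre on 14 amino acids in both, with means of 13.95 and 14.08.

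J alpha genes that lie nearest to the V alpha genes (those numbered 40 or above) were in 27.5% of WT clonotypes (58 of 211, 21.6 to 34.0) and 17.9% of p53 KO clonotypes (30 of 168, 12.4 to 24.5). The intervals overlap. The share was lower in p53 KO under all 5 alternatives, and with 3 or more UMIs per contig it was 29.4% in WT and 13.7% in p53 KO.

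The libraries had almost no receptors in common. Of 216 paired WT receptors and 177 paired p53 KO receptors, told apart by V genes and CDR3 nucleotides, 0 were found in both. Over all cells with a beta chain, 0 of the beta chain nucleotide sequences were found in both. By amino acids, 1 paired receptor was in both: TRAV12D-2 and TRAJ21 with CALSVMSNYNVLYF, and TRBV12-2+TRBV13-2 and TRBJ2-7 with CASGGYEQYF. In WT it belonged to a clonotype of 4 cells, and in p53 KO it was in 1 cell. The CDR3 of each chain differed at 1 base between the libraries. No cell barcode was found in both libraries.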

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

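The tests in this part were chosen after the values were seen. Among the main comparisons, cells with only 1 of the 2 chains entered only the count of beta chains shared between the libraries. Some chains recurred among such cells more often than a count of 0 allows (3). In the p53 KO library, the alpha chain TRAV6-6 with TRAJ18 (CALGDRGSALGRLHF) had no beta chain in 11 of its 16 cells. The alpha chain TRAV3-3 with TRAJ39 (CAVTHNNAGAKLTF) had none in 7 of its 11 cells. The beta chain of the second largest p53 KO clonotype (TRBV19, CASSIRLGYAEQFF) had no alpha chain in 14 of its 31 cells, and its alpha chain had a median of 1.5 UMIs where it was found. In WT, the alpha chains TRAV3D-3 with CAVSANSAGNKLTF and TRAV13-2 with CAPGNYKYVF lacked a beta chain in 5 of 8 and 5 of 6 cells. Chains mostly without a partner were thus found in both libraries, but the alternative that leaves out 2 alpha chains drops only p53 KO ones. The WT alpha chain TRAV7D-4 with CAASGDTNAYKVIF lacked a beta chain in 4 of 8 cells. The WT beta chain TRBV1 with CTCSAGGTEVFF lacked an alpha chain in 4 of 7 cells.

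The TRAV6-6 and TRAV3-3 chains stand out because their remaining 9 cells held 9 different beta chains, 5 and 4, while each alpha chain had 1 nucleotide sequence. Free RNA of these alpha chains would give few UMIs per cell, but their median was 1.5 times that of the other alpha contigs of the library (6 against 4 UMIs). Capture together with a T cell of another clone would often leave that cell's alpha chain behind, as 73.8% of p53 KO cells with a beta chain had an alpha chain, but 0 of the 9 cells held a second one (exact upper limit 33.6%). Still, 1 TRAV6-6 cell held 2 beta chains, as such capture would give, so it stays open for that cell. For TRAV6-6, a candidate explanation is a beta chain of its own that assembly often misses: the only beta chain found in 2 of its cells (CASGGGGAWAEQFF, 18 UMIs in each) has a run of 13 identical bases in its CDR3, against at most 9 in the other 230 beta sequences. This candidate was written down after the values were seen, so the run is no test of it. It also leaves the other beta chains of the TRAV6-6 cells unexplained. No such chain was seen for TRAV3-3, and the tumour genotype was not tested as a biological explanation.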

How the results depend on the processing

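The pooled V gene names, the count of each alpha chain nucleotide sequence once and the omissions of the 2 alpha chains and of 1 invariant NKT cell were chosen after seeing the data. Over the values that answer the comparisons, 141 of 159 alternative values stayed within set bounds of the reported one, 14 moved further and 4 turned direction. The bounds were counting error for shares and the spread of random deals for usage distances. For numbers of clonotypes they were a factor of 1.5, and for shared receptors the same count. The 141 include values that could not change, such as p53 KO shares at equal cell number. They also include the fall from 7.60 to 0.880 points in the difference for clonotypes of 2 or more cells. The larger share of the 10 largest clonotypes in p53 KO kept its direction under all 8 alternatives tried for it, with differences of 13.1 to 19.7 percentage points. Requiring 3 or more UMIs per contig leaves fewer cells. It gave a WT share in clonotypes of 2 or more cells of 27.7% (p53 KO minus WT 16.4 points), a WT share of the 10 largest clonotypes of 20.5%, and 127 and 102 clonotypes at equal cell number. It also gave usage distances of 27.0% (TRBV), 48.3% (TRAV) and 40.2% (TRAJ), against upper ends of random dealing, which rise with fewer clonotypes, of 30.6%, 51.5% and 38.2%. The WT share in clonotypes of 2 or more cells was 44.2% by TRB nucleotides and 46.0% by TRB amino acids, each over all 326 cells with a TRB and so with both the definition and the cells changed, and 46.6% over all 408 cells with any chain. The cause was not tested. Counting cells gave usage distances of 27.3% (TRBV) and 47.1% (TRAV), above dealt upper ends of 20.4% and 33.4%, which treat the cells of a clone as independent. Pooling TRAV genes by family gave 16.7% (dealt upper end 21.6%), as there are fewer classes. The difference in CDR3 beta of 14 or more amino acids ranged from 3.02 to 11.7 points, and that in V-proximal J alpha genes from -15.7 to -8.83 points. The hydropathy difference, p53 KO minus WT, turned to -1.09 points by cells, -2.53 without the 10 largest clonotypes, -4.17 with 3 or more UMIs and -2.34 over all cells with the chain, and the cause was not tested. Among named genes, 17 of 103 alternative ratios of p53 KO to WT share moved by over 1.5 times, 10 of them by cells and 4 with 3 or more UMIs. In all 7 ratios crossed 1. From ratios past the factor of 1.5, TRBV1 (1.45), TRAJ37 (1.77) and TRAV3-3 (0.980) did so by cells. From ratios nearer to 1 they were TRBV12-2+TRBV13-2 (1.08, without the 10 largest clonotypes), TRBV13-1 (1.04, all cells with the chain), TRBJ2-5 and TRAV7D-2 (1.07 each, 3 or more UMIs). No paired analysis was possible because each group has 1 library, which also rules out leaving out replicates. Depth limits the shares near 0, those of invariant NKT and MAIT chains.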

Other observations

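Except for the comparison of barcodes, the tests in this part were chosen after the values were seen, and so were the genes named in the next sentences. TRBV29 was in 3 of 211 WT and 8 of 168 p53 KO clonotypes, and TRBV31 in 1 and 6. The TRAV4 family was in 14 WT and 3 p53 KO clonotypes, and the TRAV8 family in 4 and 10. The TRAV7 family was in 24 WT and 20 p53 KO clonotypes, but in 35 WT and 76 p53 KO cells, as 4 of the 5 largest p53 KO clonotypes used it. The counting intervals over clonotypes overlap between the libraries for each of these genes and families. TRAV1 alpha chains, with J genes other than TRAJ33, were in 0 of 359 WT cells with an alpha chain, which allows up to 0.836%, and in 4 of 300 p53 KO cells (1.33%, 0.364 to 3.38).

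The libraries differed in which chain was missing. Cells with an alpha chain only were 82 of 408 in WT (20.1%, 16.3 to 24.3) and 41 of 392 in p53 KO (10.5%, 7.61 to 13.9). Cells with a beta chain only were 49 in WT (12.0%, 9.02 to 15.6) and 92 in p53 KO (23.5%, 19.4 to 28.0). The median UMIs per contig went the same way, with 5 for alpha and 4 for beta in WT, and 4 for alpha and 5 for beta in p53 KO. Across the libraries, 10 alpha CDR3 amino acid sequences were found in both, and 0 of them with the same nucleotides.

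The 3 largest p53 KO clonotypes held 54 cells, and technical sources of such clones were examined. Free beta chain RNA of a few cells would give few UMIs, but the median beta chain UMI count in these cells was 1.6 times that of the other 205 paired cells (8 against 5). The alpha chain of the second largest clonotype (16 cells) had a median of 1.5 UMIs against 3 in those other cells, but free alpha chain RNA in the second largest clonotype would reach cells of other clones, and the chain was in 0 of 320 cells with other beta chains (exact upper limit 1.15%) against 16 of 31 with its own (lower limit 33.1%). Barcode errors that split 1 cell over several barcodes would leave near-identical barcodes. Of 543 barcode pairs within these clonotypes, 0 differed at 2 or fewer bases, and the closest pair differed at 6. The barcodes are those of called cells after Cell Ranger processing, so errors corrected there would not show. A split of 1 cell over unlike barcodes would not show either and stays open. The number of mice per library, the chance of drawing 1 tumour with large clones, and the p53 genotype also stay open. These cannot be separated with 1 library each.

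A candidate explanation of the receptor whose amino acids were found in both libraries is RNA or reads passed between the libraries. Such transfer would keep the nucleotide sequence, but the CDR3 differed at 2 bases in all, 1 in each chain, with 5 or more UMIs for each chain in both libraries. How else the same protein came to be in both libraries was not tested.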
